A study of Trametes pubescens and Hermanssonia centrifuga with 16 samples.

How the data were processed

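The study measured messenger RNA by sequencing in 2 white-rot fungi, Trametes pubescens (strain FBCC735) and Phlebia centrifuga (strain FBCC195, listed by GEO as Hermanssonia centrifuga). White-rot fungi break down lignin along with the polysaccharides of plant cell walls. Per the labels' protocols, each fungus grew for 21 days on 2 g (dry weight) of wheat straw pieces or Norway spruce sticks, a softwood, at a moisture content of 60%, and RNA was purified by caesium chloride ultracentrifugation. The sample titles and treatment labels give a culture temperature of 15 or 25 °C, whereas the protocol text gives 25 °C for the solid cultures without naming 15 °C; samples were grouped by their titles. The protocol text also gives different temperatures for the liquid precultures, 25 °C for T. pubescens and 15 °C for P. centrifuga, so a difference between the species also holds a difference in preculture. Each combination of species, substrate and temperature had 2 libraries, which makes 8 libraries per species and 16 in all. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

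The deposited values are raw counts, 1 whole number per gene model and library, for 14451 gene models of T. pubescens and 13785 of P. centrifuga. Per the submitters' processing notes, Trimmomatic 0.36 and STAR 2.7.10a were used. The genome build, the annotation version and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense models, and reads shared by near-identical paralogs, could not be told apart. Each gene model carries a JGI identifier, a scaffold number and a model number. The files do not pair these identifiers with gene names, and no annotation was used here. The 22 gene lists fixed before the data were examined (plant cell wall enzymes, peroxidases and laccases, sugar transporters, heat shock proteins and others) were therefore not tested, and no function is given for any gene model.

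Library totals ranged from 9691925 to 13635999 counts. Genes with too few counts were removed with edgeR's filterByExpr, which left 11622 genes of T. pubescens and 11658 of P. centrifuga. The tested genes held at least 99.97% of the counts of each library. Libraries were scaled by the trimmed mean of M-values (TMM). Fold changes are therefore relative to the bulk of genes and not to the total amount of RNA. Each species was fitted on its own with edgeR 4.0.16 (R 4.3.3), with 1 mean per group over all 8 libraries and no replicate block, which leaves 4 residual degrees of freedom. Contrasts were tested with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest), and p-values were adjusted by Benjamini-Hochberg over the tested genes of that species and contrast. A gene was called at an adjusted p below 0.05. The standard error of a log2 fold change is its size divided by the square root of F. CPM, counts scaled to a common library total, were computed with the TMM-scaled library totals, and means ± SD of CPM are over the 2 libraries of a group. No gene was tested between the species, which do not share gene models.

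The share of variation was computed from sums of squares of log2 CPM with a prior count of 2, and tested by an exact permutation that relabels one factor within the levels of the other (36 relabellings, smallest possible p 0.0556). The effect of a factor was also expressed as the SD of its effect across genes after subtracting the variance between replicates. Correlations of fold changes are across genes, which are not independent replicates, and the contrasts set against each other share no library. The overlap of called genes was compared with n1 × n2 / N, the number given by independent lists. The lists come from the same fit and share each gene's estimated spread and expression level, so their overlap can exceed this number without shared effects. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom between the counts of replicates lay between 15.3 and 89.1. With 2 libraries per group, no split of 3 against 3 exists for the calls.

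The genes named were chosen by a rule fixed before the data were examined. In each contrast these are the called genes with the highest fold changes in each direction, at most 2 that rose and 2 that fell, whose libraries did not overlap between the groups and whose mean was at least 10 CPM in the higher group; the interaction had no condition on overlap. The tests were tried on simulated data with 200 changed genes per contrast, 2-fold or 4-fold. Counts were drawn from each gene's mean over all 8 libraries and its estimated dispersion, for 11622 and 11658 genes. All other genes had the same mean in each group, so recovery may differ in real contrasts where more genes change. In T. pubescens the fits recovered 13.1% of the 2-fold and 86% of the 4-fold changes for temperature on straw, 14% and 92% for temperature on spruce, 17.2% and 88% for the substrate at 15 °C, 12% and 90.9% for the substrate at 25 °C, and 5% and 51% for the interaction. In P. centrifuga the corresponding values were 55% and 94.9%, 53% and 92%, 43.4% and 96%, 58% and 95.9%, and 12% and 77.8%. The share of false calls was between 2.8% and 8.43%, except for the T. pubescens interaction, where it was 17.6%. Of the unchanged genes, 4.60% to 5.35% had an unadjusted p below 0.05, so counts of genes below that p include such genes. In these simulations a 2-fold change was thus recovered less often in T. pubescens, whose biological coefficient of variation was 0.222 against 0.161 in P. centrifuga.

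The alternatives fixed before the data were examined were RLE scaling (the size factors of DESeq2), the Wald test of DESeq2 1.42.0, no filter on low counts, an adjusted p below 0.01, a minimum change of 2-fold, a block for the replicate number, a fit of only the 4 libraries compared, a prior count of 0.5 for the shares of variation, and leaving out each library in turn, where the library left alone in its group is assumed to vary like the other groups. Scaling by library totals alone, and leaving out libraries for the shares of variation, were added after the data were seen. Plots were drawn with matplotlib.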

Results

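The transcriptomes of 2 wood-decay basidiomycetes were compared after 21 days of growth on wheat straw or on Norway spruce at 15 or 25 °C, to ask how far temperature alters the response of each fungus to plant biomass. Trametes pubescens is a white-rot fungus of deciduous wood, and Phlebia centrifuga is a white-rot fungus of spruce in boreal forests. Each of the 4 groups of a species had 2 libraries. The libraries held 9691925 to 13635999 raw counts, as deposited, and between 12223 and 12327 of 14451 gene models of T. pubescens and between 11944 and 12016 of 13785 of P. centrifuga had at least 1 count. The 10 most abundant genes of a library took a larger share of the counts on spruce than on straw. In T. pubescens this share was 6.46% ± 0.99 (SD, n = 4) on spruce and 4.77% ± 0.22 (SD, n = 4) on straw, and in P. centrifuga it was 7.85% ± 0.40 (SD, n = 4) and 6.51% ± 0.62 (SD, n = 4). An exact two-sided permutation test gave p = 0.0286 in either species, the smallest it can give with n = 4 per side. This test relabelled all 8 libraries freely, across both temperatures, and so treated the 4 libraries of a substrate as interchangeable. Relabelling within each temperature, as for the shares of variation, cannot give a permutation p below 0.0556.

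Substrate was the main axis of variation in both fungi, and temperature took a larger share in P. centrifuga. Substrate accounted for 53.1% of the variation of log2 CPM over 11622 genes in T. pubescens and 43.0% over 11658 genes in P. centrifuga. Temperature accounted for 12.1% and 26.7%, the interaction for 8.79% and 10.1%, and the replicates for 26.0% and 20.2%. The spread between replicates also enters the share of each factor and of the interaction and was not subtracted from these shares. For the interaction no corrected value was computed. For each factor the real labelling gave the highest share of all 36 relabellings, with an exact permutation p of 0.0556, the smallest possible, so the design cannot reach 0.05. In T. pubescens the next highest relabelling of temperature reached 11.6%, close to the real 12.1%, while in P. centrifuga it reached 13.9%. After subtraction of the replicate variance, the SD of the temperature effect across genes was 0.24 log2 units in T. pubescens and 0.41 in P. centrifuga, and the SD of the substrate effect was 0.69 and 0.54. The variance of the temperature effect was 0.119 times that of the substrate effect in T. pubescens and 0.571 times in P. centrifuga. With each library left out in turn, this ratio stayed between 0.0689 and 0.179 in T. pubescens and between 0.514 and 0.615 in P. centrifuga.

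**Figure D1:**
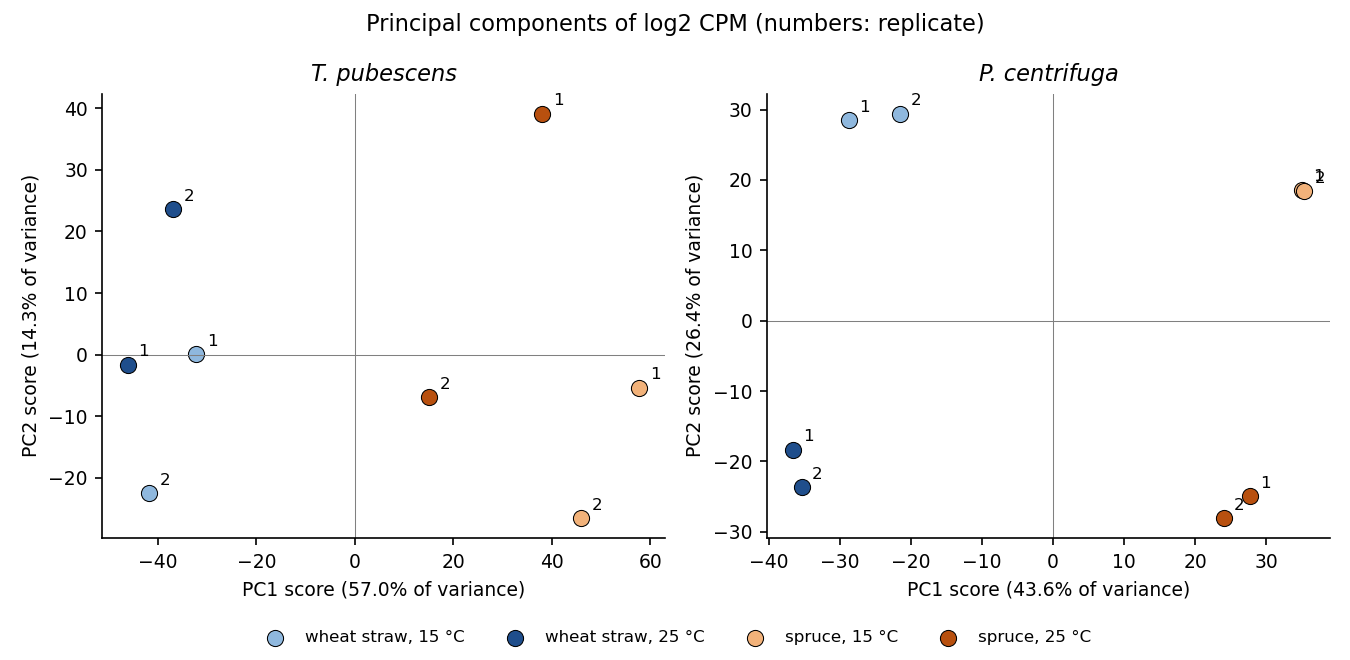
Scores of each library on the first and second principal components of log2 CPM (arbitrary units), per species, coloured by substrate and temperature and numbered by replicate. PC1 (57.0% of variance in T. pubescens, 43.6% in P. centrifuga) parts spruce from straw in both species; PC2 (14.3% and 26.4%) parts 15 from 25 °C in P. centrifuga, while in T. pubescens the temperatures overlap on it and the 2 spruce libraries at 25 °C lie apart.

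On wheat straw, 3 genes of T. pubescens differed between 25 and 15 °C. The gene jgi|Trapub1|11106|scaffold_509.14 (model 14 of scaffold 509) rose from 110 ± 2.8 CPM (SD, n = 2) at 15 °C to 1130.0 ± 173 CPM (n = 2) at 25 °C, a log2 fold change of 3.36 ± 0.28 (SE; edgeR adjusted p = 0.00633). Gene model jgi|Trapub1|11189|scaffold_520.7 rose from 39.9 ± 3.0 to 192 ± 24 CPM (log2 fold change 2.27 ± 0.21, adjusted p = 0.00942). The gene jgi|Trapub1|2738|scaffold_1325.57 fell from 15.9 ± 4.0 to 1.07 ± 0.43 CPM, 26 counts over both libraries (log2 fold change -3.87 ± 0.39, adjusted p = 0.0120). In all, 758 of 11622 genes had an unadjusted p below 0.05. In the simulated data for this contrast, 5.35% of the unchanged genes did. All 3 calls were lost when either straw library at 15 °C or the first at 25 °C was left out (0 genes called; 616, 387 and 826 at an unadjusted p below 0.05), and the count was 1, 5, 1, 103 and 51 without the first or second spruce library at 15 °C, the second straw library at 25 °C, and the first or second spruce library at 25 °C. DESeq2 called 149 genes (34 higher, 115 lower), among them these 3.

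On spruce, 39 genes of T. pubescens rose and 34 fell at 25 °C relative to 15 °C. Those that rose had a median log2 fold change of 1.84 and those that fell of -1.84, and all 73 changed by at least 2-fold. The gene jgi|Trapub1|535|scaffold_1045.45 rose from 26.0 ± 17 to 421 ± 274 CPM (n = 2 each; log2 fold change 4.01 ± 0.58, edgeR adjusted p = 0.0308), with 227 and 615 CPM in the 2 libraries at 25 °C. Gene model jgi|Trapub1|9285|scaffold_337.66 rose from 5.72 ± 0.55 to 78.1 ± 41 CPM (3.77 ± 0.42, adjusted p = 0.0146). The gene jgi|Trapub1|8613|scaffold_250.15 fell from 391.9 ± 233 to 16.0 ± 1.3 CPM (-4.61 ± 0.53, adjusted p = 0.0146), and jgi|Trapub1|8912|scaffold_295.10 fell from 421 ± 55 to 34.2 ± 5.8 CPM (-3.62 ± 0.26, adjusted p = 0.00223). None of these 4 was called in a fit of the 4 spruce libraries alone, where edgeR called 0 genes while 1141 genes had an unadjusted p below 0.05; DESeq2 on all 8 libraries called 457 genes (295 higher, 162 lower), and scaling by library totals alone gave 72 higher and 23 lower. With 1 library left out, the call of 535 was lost without either spruce library at 15 °C or either straw library at 25 °C, that of 9285 without either spruce library at 15 °C and that of 8613 without the second of these. The count of 73 became 38 without either straw library at 15 °C (17 higher, 21 lower), 4 and 1, all lower, without the first and second spruce library at 15 °C, 48 and 47 without the first and second straw library at 25 °C, and 334 and 130 without the first and second spruce library at 25 °C.

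In P. centrifuga, 756 genes rose and 607 fell at 25 °C on wheat straw, with median log2 fold changes of 1.05 and -0.81, and 604 of the 1363 changed by at least 2-fold. The gene jgi|Phlcen1|13638|scaffold_989.9 rose from 13.2 ± 3.1 to 249.7 ± 79 CPM (n = 2 each; log2 fold change 4.23 ± 0.31, edgeR adjusted p = 0.000885), and jgi|Phlcen1|12208|scaffold_673.6 rose from 64.1 ± 13 to 806 ± 81 CPM (3.65 ± 0.27, adjusted p = 0.000985). The genes with the largest falls were neighbours, models 7 and 8 of scaffold 2677. The first, jgi|Phlcen1|8301|scaffold_2677.7, fell from 348 ± 119 to 12.5 ± 4.2 CPM (-4.79 ± 0.32, adjusted p = 0.000712), and the second, jgi|Phlcen1|8302|scaffold_2677.8, fell from 229 ± 112 to 14.7 ± 5.8 CPM (-3.95 ± 0.39, adjusted p = 0.00163); in the spruce libraries both lay between 6.54 and 11.4 CPM. These 4 calls held with each library left out in turn. The count of 1363 was 254 and 422 without the first and second straw library at 15 °C, 463 and 490 without those at 25 °C, 2209 and 2203 without the spruce libraries at 15 °C (1108 higher and 1101 lower, 1101 and 1102), and 898 and 900 without those at 25 °C; scaling by library totals alone gave 1054 higher and 361 lower.

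On spruce, 673 genes of P. centrifuga rose and 451 fell at 25 °C, with median log2 fold changes of 0.89 and -0.77, and 413 of the 1124 changed by at least 2-fold. The genes with the largest rises were those named on straw. Gene 12208 rose from 17.4 ± 3.6 to 1180 ± 318 CPM (n = 2 each; log2 fold change 6.08 ± 0.31, edgeR adjusted p = 0.000474) and gene 13638 from 9.52 ± 2.3 to 112 ± 18 CPM (3.56 ± 0.30, adjusted p = 0.00203). The gene jgi|Phlcen1|8672|scaffold_2720.5 fell from 110 ± 98 to 7.51 ± 2.1 CPM (-3.87 ± 0.67, adjusted p = 0.0170), and jgi|Phlcen1|10435|scaffold_3005.30 fell from 307 ± 293 to 34.1 ± 2.6 CPM (-3.17 ± 0.75, adjusted p = 0.0412), with 99.7 and 513 CPM in the 2 libraries at 15 °C. Both falls were lost in a fit of the 4 spruce libraries alone, which called 115 genes, and without either spruce library at 25 °C; the fall of 10435 was also lost without any other single library except the first spruce library at 15 °C. The split of 673 against 451 was 634 against 762 with DESeq2, 614 against 782 without the first spruce library at 15 °C and 1205 against 248 with scaling by library totals, and the count was 536 without either straw library at 15 °C, 714 and 716 without those at 25 °C, and 212 and 85 without the first and second spruce library at 25 °C.

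**Figure D2:**
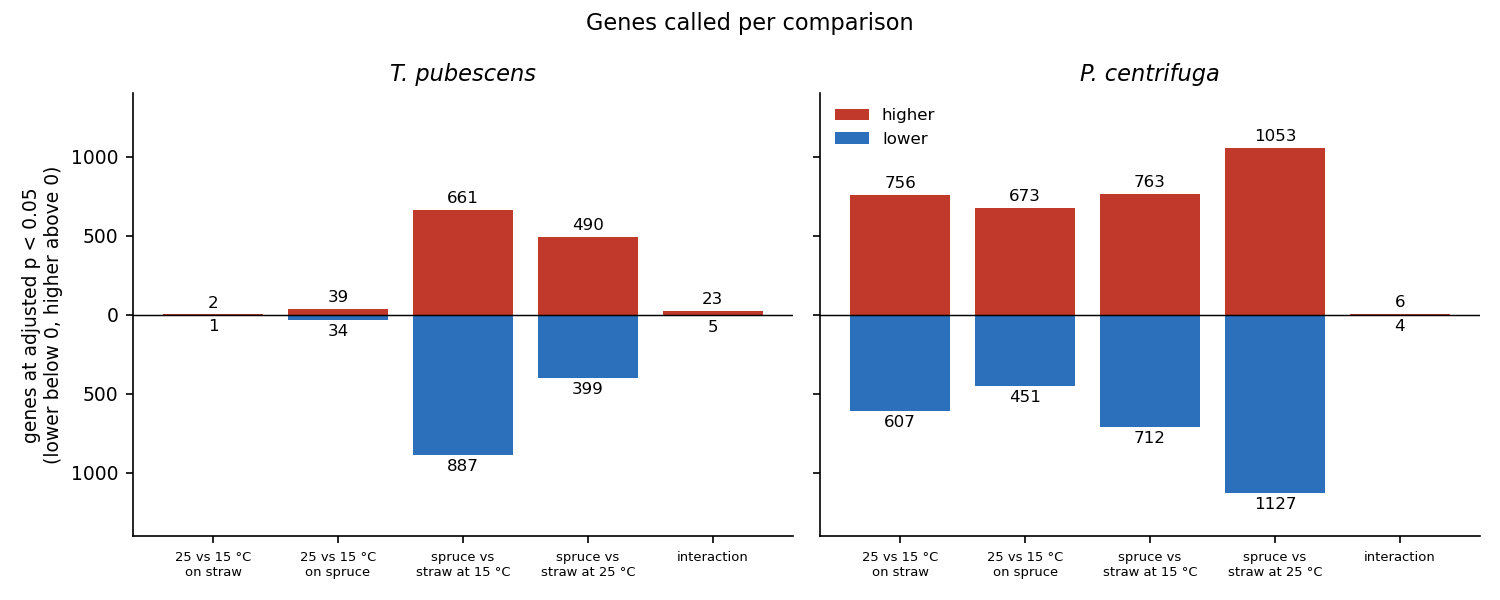
Number of genes past an adjusted p of 0.05 in each comparison (bars above 0: higher; bars below 0: lower in the first-named condition; for the interaction, higher or lower temperature effect on spruce), per species, with 2 libraries per group. Temperature called 3 and 73 genes in T. pubescens and 1363 and 1124 in P. centrifuga, while the substrate called 1548 and 889 in T. pubescens and 1475 and 2180 in P. centrifuga.

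At 15 °C, 661 genes of T. pubescens were higher and 887 lower on spruce than on straw, with median log2 fold changes of 1.38 and -1.62, and 147 genes differed by at least 8-fold (50 higher, 97 lower). The gene jgi|Trapub1|9042|scaffold_305.10 reached 4133 ± 2001 CPM on spruce against 36.6 ± 12 on straw (n = 2 each; log2 fold change 6.82 ± 0.80, edgeR adjusted p = 0.000814), and jgi|Trapub1|3557|scaffold_1431.24 reached 347 ± 115 against 3.7 ± 0.63 CPM (6.54 ± 0.50, adjusted p = 0.000174). Gene model jgi|Trapub1|9415|scaffold_354.3 was lower on spruce, 1.25 ± 0.08 against 170 ± 113 CPM (-7.06 ± 0.78, adjusted p = 0.000696), as was jgi|Trapub1|11954|scaffold_644.23, 2.46 ± 1.3 against 243 ± 143 CPM (-6.59 ± 0.92, adjusted p = 0.00183). Expression of 6 called genes went from at least 10 CPM on straw to under 1 CPM on spruce. The split between directions depended on the scaling, with 367 higher and 1920 lower when libraries were scaled by their totals alone, which moved the median log2 fold change of all genes to -0.34. The count of 1548 was 757 and 653 without the first and second straw library at 15 °C, 495 and 728 without the spruce libraries at 15 °C, 2369 without the first spruce library at 25 °C and 2564 in a fit of the 4 libraries alone.

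At 25 °C, 490 genes of T. pubescens were higher and 399 lower on spruce, with median log2 fold changes of 1.55 and -1.60, and 77 differed by at least 8-fold (46 higher, 31 lower). Gene 9042 again had the largest rise, at 610 ± 556 against 9.46 ± 2.9 CPM (n = 2 each; 6.01 ± 0.78, edgeR adjusted p = 0.00231), with 217 and 1004 CPM in the spruce libraries. Gene model jgi|Trapub1|4872|scaffold_1556.21 stood at 383 ± 91 against 7.78 ± 2.3 CPM (5.62 ± 0.39, adjusted p = 0.000244). Genes 9415 and 11954 again had the largest falls, to 2.52 ± 2.3 CPM from 275 ± 91 (-6.78 ± 0.74, adjusted p = 0.00118) and to 7.34 ± 7.7 CPM from 391 ± 158 (-5.74 ± 0.86, adjusted p = 0.00399). Expression of 2 called genes went from under 1 CPM on straw to at least 10 CPM on spruce. The 8 named substrate calls of T. pubescens held in each setting tried. The count of 889 was 307 and 422 without the first and second straw library at 25 °C and 514 in a fit of the 4 libraries alone, and the majority was lower with scaling by library totals (331 higher, 590 lower) and without the second straw library at 25 °C (202 and 220).

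In P. centrifuga at 15 °C, 763 genes were higher and 712 lower on spruce than on straw, with median log2 fold changes of 0.93 and -1.11, and 51 differed by at least 8-fold (20 higher, 31 lower). Gene model jgi|Phlcen1|9885|scaffold_2906.3 stood at 76.1 ± 13 CPM on spruce against 2.06 ± 0.32 on straw (n = 2 each; log2 fold change 5.21 ± 0.28, edgeR adjusted p = 0.000271), and jgi|Phlcen1|11603|scaffold_541.4 at 929.6 ± 314 against 49.6 ± 4.3 CPM (4.23 ± 0.31, adjusted p = 0.00069). Gene model jgi|Phlcen1|1822|scaffold_1388.1 had 4632 counts in the straw libraries and 4 in the spruce libraries, 216 ± 9.4 against 0.203 ± 0.13 CPM (-9.93 ± 0.31, adjusted p = 2.78e-05). The gene jgi|Phlcen1|7673|scaffold_2626.21 stood at 10.8 ± 8.8 CPM on spruce against 825 ± 270 on straw (-6.24 ± 0.63, adjusted p = 0.00224). Expression of 2 called genes went from at least 10 CPM on straw to under 1 CPM on spruce, at 15 as at 25 °C. The 4 named calls held in each setting tried. The split of 763 against 712 turned to 619 higher and 835 lower with scaling by library totals alone, to 117 and 235 and 319 and 354 without the first and second straw library at 15 °C (352 and 673 genes), and to 265 and 270 in a fit of the 4 libraries alone (535 genes).

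At 25 °C, 1053 genes of P. centrifuga were higher and 1127 lower on spruce, with median log2 fold changes of 0.81 and -0.92, and 45 differed by at least 8-fold (13 higher, 32 lower). Gene model jgi|Phlcen1|1724|scaffold_1359.12 stood at 187 ± 5.9 against 5.49 ± 1.3 CPM (n = 2 each; 5.09 ± 0.60, edgeR adjusted p = 0.00312), and jgi|Phlcen1|5850|scaffold_2287.5 at 518 ± 86 against 18.3 ± 2.1 CPM (4.82 ± 0.44, adjusted p = 0.00144). Gene 1822 was again lower on spruce, 0.67 ± 0.13 against 91.7 ± 19 CPM (-7.06 ± 0.25, adjusted p = 8.83e-05). Gene model jgi|Phlcen1|9950|scaffold_2917.24 was called lower on spruce (-5.37 ± 1.48, adjusted p = 0.0436), but its straw libraries held 202 and 6.25 CPM and its spruce libraries 3.06 and 1.98. The call was lost in a fit of the 4 libraries compared, and without 5 of the 8 libraries in turn, the first straw library at 25 °C among them. The count of 2180 was 1404 without either straw library at 15 °C, 604 and 927 without the first and second straw library at 25 °C, and 466 and 498 without the spruce libraries at 25 °C, with 297 higher and 201 lower without the second of these.

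**Figure D3:**
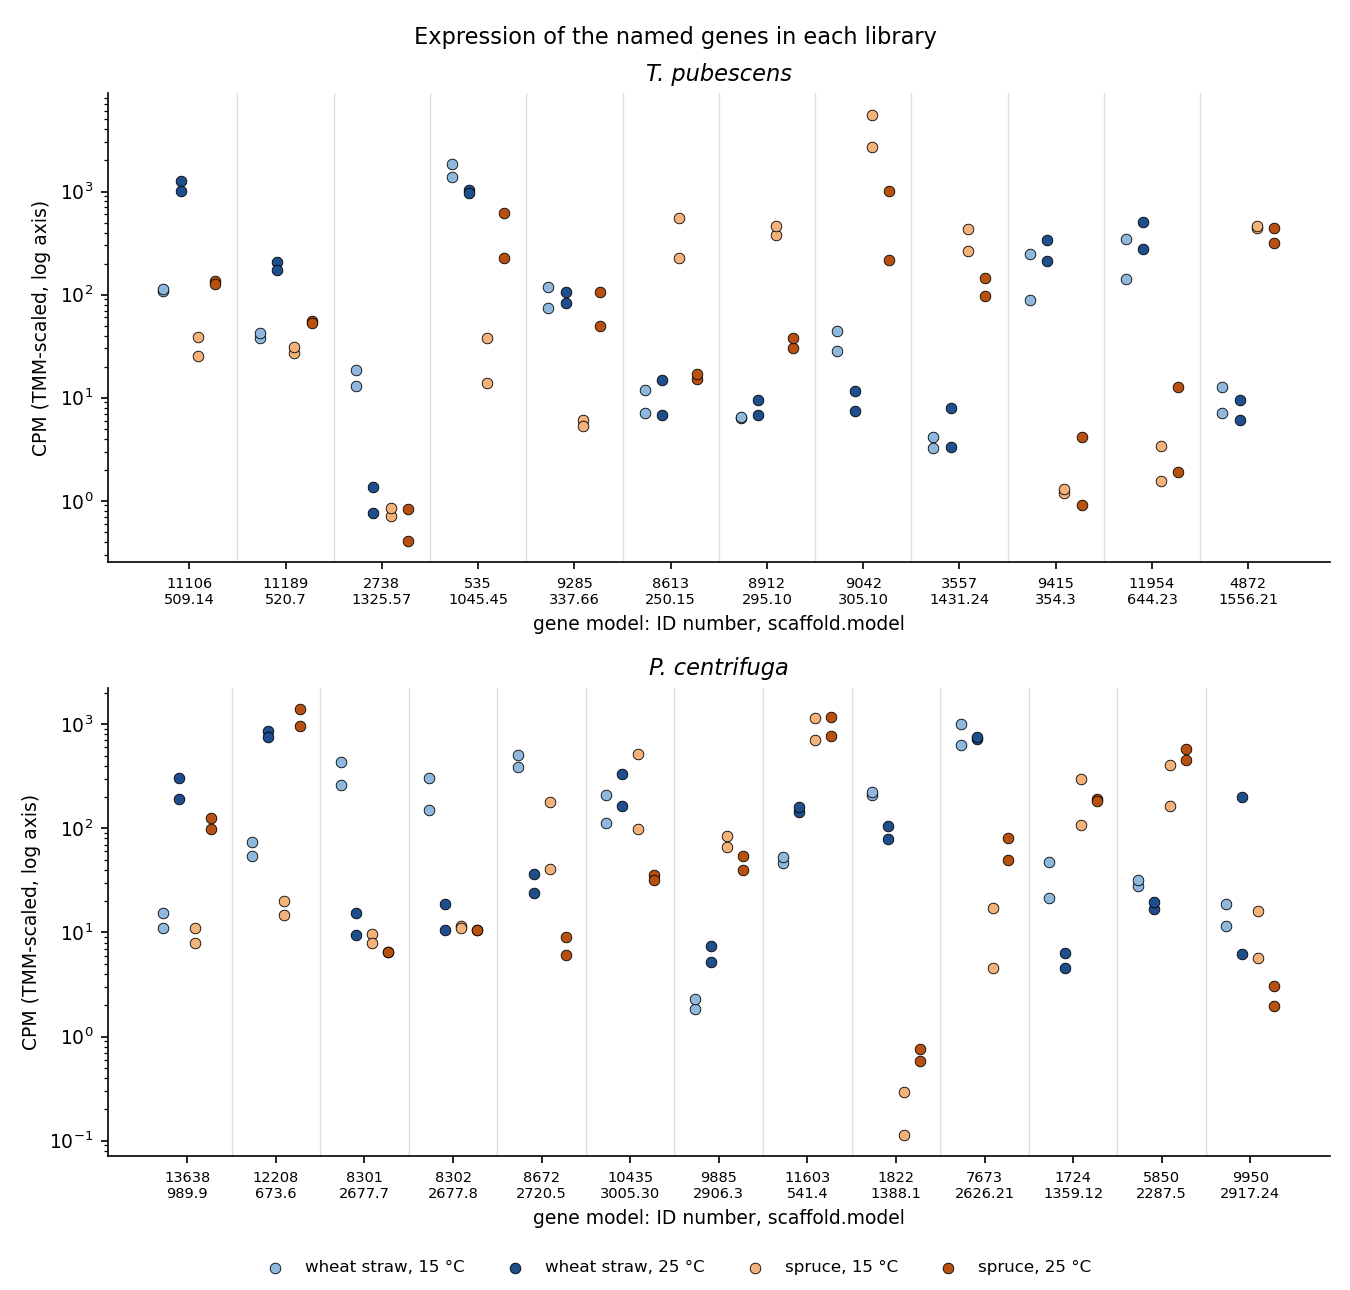
Expression of the named genes of T. pubescens (upper panel) and P. centrifuga (lower panel) in CPM (counts scaled to a common library total) on a log axis; each point is 1 library, coloured by substrate and temperature, with 2 points per group. Gene 9042 of T. pubescens lies between 217 and 5548 CPM in the spruce libraries and between 7.39 and 44.8 CPM in the straw libraries, and gene 12208 of P. centrifuga lies between 748 and 1405 CPM at 25 °C and between 14.9 and 73.7 CPM at 15 °C.

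Most genes called between substrates at 1 temperature had the same sign at the other, called there or not. The sign was the same at 25 °C for 1439 of the 1548 genes of T. pubescens and 1322 of the 1475 of P. centrifuga called at 15 °C, and at 15 °C for 847 of 889 and 1855 of 2180 called at 25 °C. Across genes, which are not independent replicates, the log2 fold changes of spruce against straw at 15 and 25 °C had a Pearson r of 0.718 (Spearman 0.684) in T. pubescens and 0.597 (0.488) in P. centrifuga, between contrasts that share no library. Lists from the same fit share each gene's estimated spread and expression level, which can by itself raise the overlap above that of independent lists. In T. pubescens, 305 genes were called higher on spruce at both temperatures, against 27.9 for independent lists. There 292 were called lower at both, against 30.5, and 5 were called in opposite directions. In P. centrifuga the numbers were 376 against 68.9, 332 against 68.8, and 9. The r across genes of the temperature effects on straw and on spruce was 0.213 (Spearman 0.192) in T. pubescens and 0.441 (0.375) in P. centrifuga. In P. centrifuga, 334 genes rose at 25 °C on both substrates, against 43.6 for independent lists, 115 fell on both, against 23.5, and 9 went in opposite directions. In T. pubescens 1 gene was called on both substrates, and 35 of the 73 genes called on spruce (47.9%) had the same sign on straw. Without 1 library, the r of the temperature effects in T. pubescens lay between 0.0599 and 0.239.

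**Figure D4:**
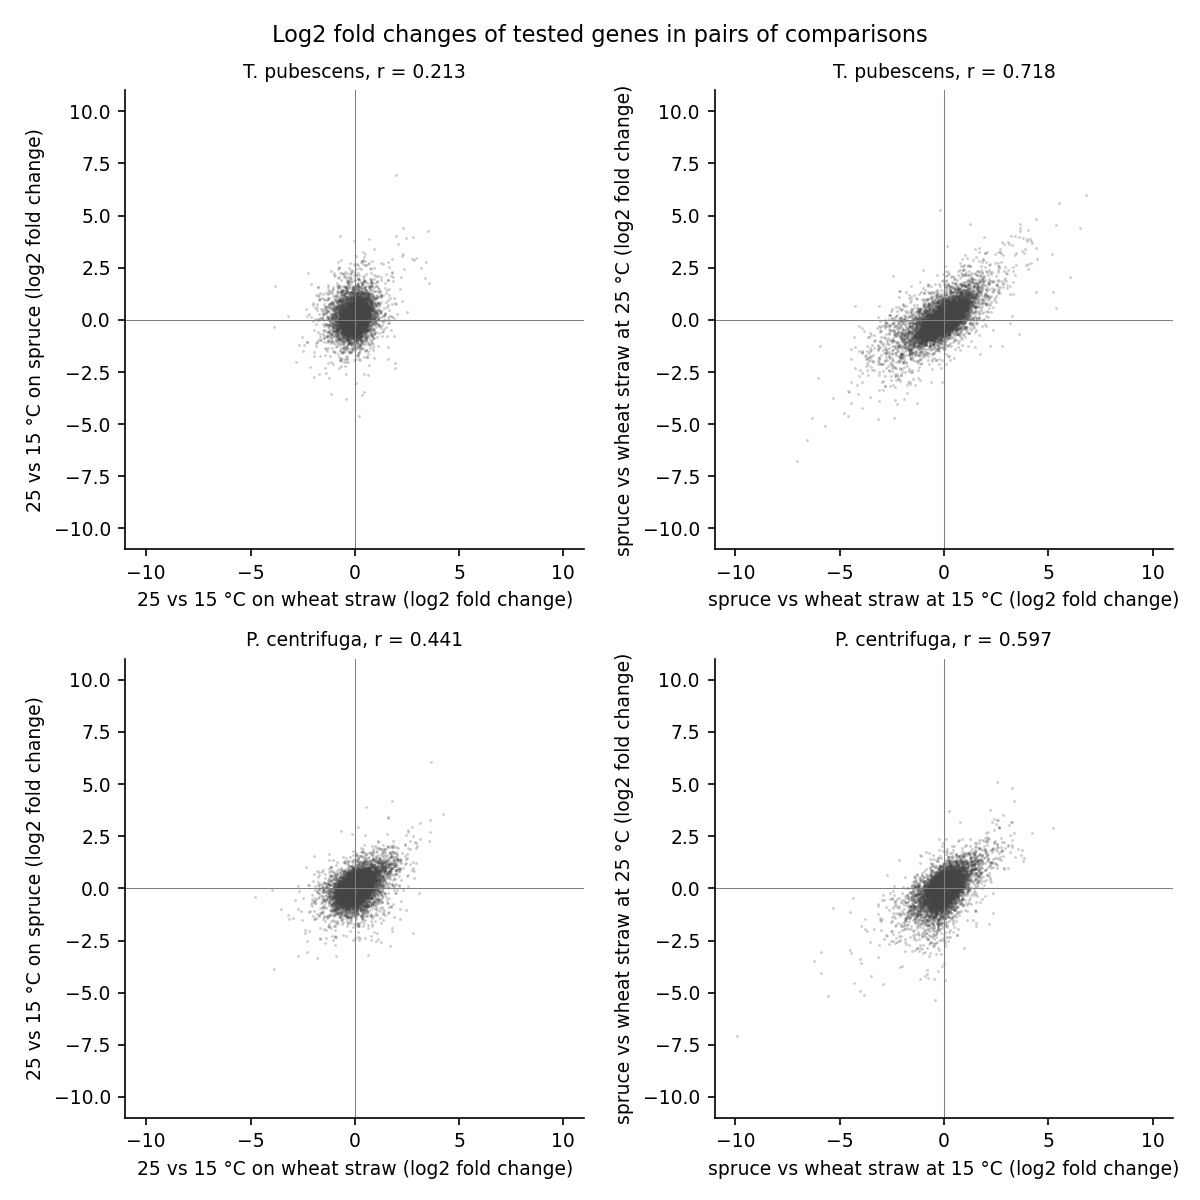
Log2 fold change of each tested gene (1 point per gene) in 1 comparison against another that shares no library: temperature on straw and on spruce (left) and substrate at 15 and 25 °C (right), for T. pubescens (top, 11622 genes) and P. centrifuga (bottom, 11658 genes). The substrate effects spread along the diagonal (r = 0.718 and 0.597), and the temperature effects have r = 0.213 and 0.441.

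The test of whether temperature acted differently on the 2 substrates called 28 genes in T. pubescens, with a temperature effect higher on spruce in 23 and lower in 5. Of the 23, 22 were also called lower on spruce than on straw at 15 °C, and their median log2 fold change between substrates was -2.49 at 15 °C and 0.21 at 25 °C; these values come from the same libraries as the test. Of the 5, all were called higher on spruce at 15 °C, where their median was 3.24, against 0.21 at 25 °C. In P. centrifuga 10 genes were called, 6 with a higher and 4 with a lower temperature effect on spruce. The number of interaction calls depended on the setting, and RLE scaling called 1 gene in either species. DESeq2 called 227 genes in T. pubescens (160 higher, 67 lower) and 414 in P. centrifuga (183 higher, 231 lower), where the majority thus turned. With 1 library left out, edgeR called 0 genes of T. pubescens without either library at 15 °C on either substrate or the first straw library at 25 °C (635 to 833 genes at an unadjusted p below 0.05), and 1, 186 and 57 without the second straw library and the first and second spruce library at 25 °C. In P. centrifuga it called 0 without the first straw library at 15 or 25 °C or either spruce library at 25 °C (1282 to 1636 genes at an unadjusted p below 0.05), 6 and 17 without the second straw library at 15 and 25 °C, and 192 and 82 without the first and second spruce library at 15 °C.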

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

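The test reported here was fixed before the data were examined. The effect of temperature differed between wheat straw and spruce, by edgeR's interaction test, for 28 genes of T. pubescens and 10 genes of P. centrifuga. In the simulated data, 17.6% of the interaction calls were false in T. pubescens and 3.26% in P. centrifuga. Values below are the log2 difference between the temperature effect on spruce and that on straw, with its SE.

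In T. pubescens the difference was 3.80 ± 0.55 for jgi|Trapub1|9285|scaffold_337.66 (adjusted p = 0.0424), whose mean was 5.72 CPM on spruce at 15 °C and 78.1 to 96.4 CPM in the other groups. It was 3.49 ± 0.44 for jgi|Trapub1|7990|scaffold_175.3 (adjusted p = 0.0421), which stood at 4.64 CPM on spruce at 15 °C, 23.9 on spruce at 25 °C, 20.1 on straw at 15 °C and 9.19 on straw at 25 °C. It was -4.81 ± 0.70 for jgi|Trapub1|8613|scaffold_250.15 (adjusted p = 0.0424) and -3.98 ± 0.36 for jgi|Trapub1|8912|scaffold_295.10 (adjusted p = 0.0163), at 391.9 and 421 CPM on spruce at 15 °C and 16.0 and 34.2 CPM on spruce at 25 °C. On straw these 2 genes stood at 6.4 to 10.8 CPM.

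In P. centrifuga the difference was 4.37 ± 0.44 for jgi|Phlcen1|8301|scaffold_2677.7 (adjusted p = 0.0475), at 348 CPM on straw at 15 °C and 6.54 to 12.5 CPM in the other groups. It was 2.79 ± 0.30 for jgi|Phlcen1|307|scaffold_1053.13 (adjusted p = 0.0475), at 488 CPM on spruce at 25 °C and 63.1 on spruce at 15 °C, against 159 and 142 on straw. It was -2.03 ± 0.15 for jgi|Phlcen1|7655|scaffold_2626.3 (adjusted p = 0.0209), at 85.3 CPM on straw at 25 °C and 11.8 to 27.9 CPM in the other groups. It was -1.77 ± 0.21 for jgi|Phlcen1|6053|scaffold_2338.5 (adjusted p = 0.0475), at 27.8 CPM on spruce at 15 °C and 10.2 to 16.3 CPM in the other groups. With 1 library left out, the 4 T. pubescens calls were each lost without either library at 15 °C on either substrate and without the first straw library at 25 °C, and those of 9285, 7990 and 8613 also without the second. The 4 P. centrifuga calls were each lost without the first straw library at 15 or 25 °C and without either spruce library at 25 °C, those of 7655 and 6053 also without the second straw library at 15 °C, and those of 307 and 6053 without the second at 25 °C. With RLE scaling the calls of 9285, 7990, 8613, 8301, 307 and 6053 were lost, and with libraries scaled by their totals alone that of 8613.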

How the results depend on the processing

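Scaling by library totals alone, and leaving out libraries for the shares of variation, were chosen after the data were seen. No called gene changed sign in any setting that tested it. Of 39 results for single named genes, 21 stayed past the threshold in every setting and 0 reversed. The count of calls moved by over 1.5 times as follows, with counts for temperature on straw and on spruce, substrate at 15 and 25 °C and the interaction named as such; the causes were not tested, except that stricter thresholds call fewer genes by construction. At an adjusted p below 0.01, T. pubescens kept 1 gene for temperature on spruce, 651 and 338 for the substrate and 0 for the interaction (914 at an unadjusted p below 0.05), and P. centrifuga kept 414 and 193 for temperature, 535 and 537 for the substrate and 0 for the interaction (2114 at an unadjusted p below 0.05). With at least 2-fold required, P. centrifuga kept 604 and 413 for temperature and 744 and 887 for the substrate. DESeq2 called 149 and 457 genes for temperature and 227 for the interaction in T. pubescens, and 414 for the interaction in P. centrifuga. Without the filter, 18 genes were called for temperature on straw in T. pubescens. RLE scaling called 1 interaction gene in either species, and library totals alone called 18 and 19. That scaling moved the median log2 fold change of all genes in T. pubescens to -0.34 and -0.20 for the substrate at 15 and 25 °C, 0.18 for temperature on spruce and 0.14 for the interaction, and in P. centrifuga to 0.11 and 0.16 for temperature on straw and spruce. A fit of the 4 libraries compared called 20 and 0 genes for temperature (1141 on spruce at an unadjusted p below 0.05) and 2564 and 514 for the substrate in T. pubescens, and 115 for temperature on spruce and 535 for the substrate at 15 °C in P. centrifuga. Leaving out 1 library at a time, a fit in which 1 group holds a single library, gave 0 to 103 genes for temperature on straw, 1 to 334 on spruce, 495 to 2369 and 307 to 1297 for the substrate at 15 and 25 °C and 0 to 186 for the interaction in T. pubescens, and 254 to 2209, 85 to 1548, 352 to 1919, 466 to 3155 and 0 to 192 in P. centrifuga. The correlation across genes of the temperature effects lay between 0.0599 and 0.239 in T. pubescens and between 0.341 and 0.511 in P. centrifuga, and that of the substrate effects between 0.59 and 0.695 and between 0.53 and 0.625. The share of variation lay between 10.8% and 14.8% for temperature and between 46.9% and 54.6% for the substrate in T. pubescens, and between 24.2% and 27.9% and between 38.4% and 43.5% in P. centrifuga; the ratio of effect variances lay between 0.0689 and 0.179 and between 0.514 and 0.615. The replicate numbers are shared between groups in the labels, but the deviations of same-numbered libraries from their group means correlated between -0.194 and 0.438 over the 6 pairs of groups in T. pubescens and between -0.32 and 0.264 in P. centrifuga (3 pairs in T. pubescens above 0.3 and 3 below -0.1; 3 pairs in P. centrifuga above 0.1). Since not every pair lay above 0.1, and the labels tie no number to a shared batch, the numbers were not taken to pair the samples; a batch shared by some of the groups is not excluded. A replicate block called 22 and 163 genes for temperature and 65 for the interaction in T. pubescens, and 0 for the interaction in P. centrifuga (1988 at an unadjusted p below 0.05); its other counts stayed within 1.5 times. Other columns for strand are not in the files used, and the gene lists could not be matched to the identifiers, so the alternatives for both were not run. Library totals of 9691925 to 13635999 counts limit what can be said of the genes removed by the filter.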

Other observations

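The tests of the most abundant genes, of effect sizes per contrast, of the bootstrap intervals for a straw share and for the genes below its level, and of the explanations for the fewer temperature calls in T. pubescens were chosen after the results were seen; the other tests in this part were set out before their results were seen.

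The most abundant genes of either substrate were followed in the contrasts between substrates. For each contrast the 100 most abundant genes were ranked on 1 group at the other temperature, so that no library of the contrast chose them; a gene that spruce raises at either temperature can still enter the spruce list for that reason. In T. pubescens, of the 100 genes ranked on spruce, 49 were called higher and 2 lower on spruce at 15 °C, and 43 higher and 0 lower at 25 °C, and they took 25.2% of the counts on spruce and 16.0% on straw at 15 °C and 21.8% and 13.2% at 25 °C, as means of 2 libraries. Of the 100 ranked on straw, 15 were called higher and 15 lower at 15 °C, and 17 higher and 8 lower at 25 °C, and they took 16.9% and 17.5% at 15 °C and 19.0% and 17.1% at 25 °C; the difference between the lists was not tested. With libraries scaled by their totals alone, the spruce lists gave 34 higher and 5 lower at 15 °C and 40 and 0 at 25 °C, and the straw lists 7 and 29 and 15 and 9. With 1 library left out, the 49 became 22 and 26 without the first or second straw library and 25 without the first spruce library at 15 °C, and the 43 became 17 and 22 without the first or second straw library at 25 °C. The straw lists then gave 4 higher and 13, 12 and 12 lower without the first or second straw library or the first spruce library at 15 °C, and 6 and 13 without the second straw library at 25 °C; for the contrast at 25 °C they gave 3 higher and 6 or 7 lower without the first or second straw library at 25 °C. In P. centrifuga the spruce lists gave 16 higher and 10 lower at 15 °C and 24 and 7 at 25 °C, and the straw lists 5 higher and 23 lower and 11 and 23; with 1 library left out the spruce lists gave 5 to 22 higher and 3 to 11 lower at 15 °C and 9 to 28 and 0 to 15 at 25 °C, and the straw lists 2 to 11 and 6 to 22 at 15 °C and 3 to 13 and 4 to 33 at 25 °C. The SD of the substrate effect across genes, after subtraction of the replicate variance, was 0.80 log2 units at 15 °C and 0.59 at 25 °C in T. pubescens, and 0.55 and 0.59 in P. centrifuga.

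Genes with the same response to the substrate often lay beside each other. In T. pubescens 250 pairs of adjacent gene models were called in the same direction at 15 °C, against a mean of 97.9 in 1000 shuffles among genes of like expression, and 133 pairs at 25 °C, against 32.0. In P. centrifuga there were 241 pairs against 87.4 at 15 °C and 419 against 188 at 25 °C. Temperature gave 191 pairs against 72.7 on straw and 141 against 51.7 on spruce in P. centrifuga. In T. pubescens it gave 0 pairs on straw, where 3 genes were called, and 3 against 0.204 on spruce. The log2 fold changes of adjacent models correlated with r between 0.204 and 0.244 for the substrate and between 0.143 and 0.212 for temperature. The lowest r was that of T. pubescens on straw, so neighbours were somewhat alike also where few genes were called. Models 40 to 45 of scaffold 1045 of T. pubescens, which include the named gene 535, were each lower on spruce at 15 °C, with a median log2 fold change of -2.72. Models 3 to 6 of scaffold 895 of P. centrifuga each rose at 25 °C on both substrates, with medians of 1.87 on straw and 1.69 on spruce, as did models 8 to 10, with 2.02 and 1.51. Models 5 to 8 of scaffold 606 of P. centrifuga were each higher on spruce than on straw at 15 °C (median 2.10). On spruce the same models each fell at 25 °C relative to 15 °C (median -1.15). Runs and single scaffolds were picked after their values were seen.

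Chance placement does not account for this clustering. The smallest ratio of observed to shuffled pairs, over both species and both temperatures, was 2.23, and each of the 4 observed counts exceeded all 1000 shuffles (one-sided permutation p = 0.001, the smallest possible). A hypothesis is that such runs are gene clusters regulated together. Tandem copies that share reads, overlapping models counted without strand, and single genes split into several models may also place like responses side by side. None of these was tested, because the sequences and the annotation of the models were not used here, and the model number is assumed to follow the order on the scaffold.

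Fewer genes were called for temperature in T. pubescens (3 on straw and 73 on spruce) than in P. centrifuga (1363 and 1124). DESeq2 called 149 and 457 in T. pubescens and 1479 and 1396 in P. centrifuga, so the size of the gap depended on the test. A larger spread between replicates in T. pubescens lowers the number of calls, but after that spread was subtracted the variance of the temperature effect in T. pubescens was still 0.342 times that in P. centrifuga, and between 0.185 and 0.601 times over all pairs of fits that left out up to 1 library per species. The ratio of median library totals between the species was 0.997. With the effect averaged over both substrates, the spread and the depth are therefore not the whole cause. On straw, the corrected SD of the temperature effect across genes was 0.22 log2 units in T. pubescens and 0.48 in P. centrifuga. On spruce it was 0.33 and 0.42, so the species lay closer there. The part of the spruce gap in calls that the spread explains was not tested. A difference between the species in their response to temperature, the different preculture temperatures and differences in how the 2 annotations were made remain untested. Each of these may account for the fewer calls.

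The 2 T. pubescens libraries from spruce at 25 °C differed more than the libraries of any other group, with a mean squared log2 difference of 0.423 against 0.0882 to 0.272 in the other 7 groups, and the second lay nearer to the straw libraries on the first component. After the first library was thinned to the total of the second, the difference was 0.428, above the highest of the other 3 T. pubescens groups, 0.256. Thinning adds sampling noise and could hardly lower the difference, so it cannot decide whether unequal depth plays a part. Low totals do not set this pair apart. It held 13635999 and 10698298 counts, while the T. pubescens pair from spruce at 15 °C held 10180387 and 11887311 and differed by 0.195. RNA of a straw culture in the second library was tested on 27 genes specific to straw, chosen without these 2 libraries. The median loss of 20 spruce-specific genes asks for a straw share of 24.1% (95% bootstrap interval -3.26 to 31.8). With that share taken as known, the straw-specific genes gave a median of 8.0% (0.393 to 10.6), so the 2 values are not independent. Relative to the first library, 14 of the 20 spruce-specific genes were lower in the second and 16 of the 27 straw-specific genes were higher. Of the straw-specific genes, 25.9% (95% exact interval 11.1 to 46.3) lay below the level that 24.1% would need. Under 10% had been set beforehand for a mixture and at least 25% against it. The exact interval lies above 10% but takes the 24.1% as known. With that share resampled as well the interval is 0 to 55.6, across both bounds. A straw share and a true difference between the cultures therefore stay open. The deviations of this pair also correlated with those of the same-numbered libraries at 15 °C, on straw (r = 0.429) and on spruce (0.438). For straw at 25 °C the r was -0.141. A batch shared by some of the groups was not tested and stays open as well. With these 2 libraries the explanations cannot be told apart.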
